A study of Mus musculus with 6 samples.

How the data were processed

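Total RNA from BCR-ABL1-transformed mouse pre-B cells was biotin-labelled and hybridised to 6 Affymetrix arrays, per the labels' protocols. The cells carried floxed Spry1 and Spry2 alleles on the FvB/N background. They had been transduced with a vector for ERT2 alone (control, 3 arrays) or for the tamoxifen-inducible recombinase Cre-ERT2 (3 arrays), and both groups had received 0.5 µM 4-hydroxytamoxifen for 2 days. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

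The deposited value table holds log2 expression values from 2.47 to 14.81 for 35556 probes. Robust multi-array averaging (RMA) and Partek 6.5 are named in the submitters' processing notes, without a role or an order. The background correction, the probe filters and the genome build are not given in the sources used here. The values were used on the deposited log2 scale with no further scaling. The number of arrays, rather than a read depth, limits the precision: the median standard error of a log2 fold change was 0.0656.

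Probes were named through the annotation table of the array platform. Of the probes, 21789 name 1 gene, 1621 name several genes and 12146 are unnamed here. Entrez identifiers of 21698 single-gene probes matched the mouse gene table of the GRCm38.p6 assembly, and 0 symbols changed. That table was used for names only, and positions and transcript lengths were not analysed here. Probes of several genes or of no named gene were left out of the gene-level tests. For the 999 genes with several probes, the probe with the highest mean over all arrays represented the gene, which left 19938 genes. The part of Spry1 and Spry2 that their probes cover was not analysed here, so the signal left after recombination does not measure the share of undeleted alleles.

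Cre-ERT2 and control arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Fold changes are differences of mean log2 values, Cre-ERT2 minus control. For Spry1, Spry2 and the mast cell marker mean, an exact two-sided permutation test was run beside the model. With 3 arrays against 3 it cannot go below 0.1.

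The main model, the alternatives, the rule for named genes and 24 gene lists were fixed before the data were examined. The lists held 566 entries, of which 516 were measured by single-gene probes. The others were not analysed here, and 3 entries were matched through an older symbol. Lists were tested with camera at a preset correlation between genes of 0.01, with Spry1 and Spry2 left out of the set tests and adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. Each list median was also placed among the medians of 10000 random lists of genes matched on mean signal. A list of mast cell markers (22 measured) was tested on its own. It was settled after the values of 48 candidate genes (44 measured) had been viewed. The wider set was therefore summarised beside it, without a set test of its own. The named genes were the Sprouty and Spred family, the 10 genes with the largest change in each direction among those past the threshold, and up to 4 members per list with the lowest p. Predicted genes, clone names, small RNA genes, olfactory and vomeronasal receptors and antigen receptor segments were left out of the top genes. Other members of the fixed lists that are named below, and any gene said to be so, were chosen after their values were seen.

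The procedure was tested on simulated data with the real means and spreads of the 19938 genes, in 20 simulations of Cre-ERT2 against control with 200 genes changed. It recovered 15.2% of genes changed by a log2 value of 0.25, 72.9% at 0.5, 96.3% at 1 and 99.5% at 1.5. False calls made up 4.25% of the calls. Noise was drawn independently for each gene, without effects that genes share on an array, so these shares may differ on the real data. A shift of -0.15 planted in the G2/M list was called in 20 of 20 simulations of independent genes. The real G2/M genes had an estimated correlation of 0.481, so these simulations do not show how the list test performs on the real data.

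The alternatives left out genes below the 40th percentile of mean signal, averaged the probes of a gene, tested every probe, centred the arrays on their medians, repeated quantile normalization, changed the variance model, weighted the arrays, blocked on the replicate number, left out each array in turn, and moved the threshold. A covariate for the mast cell marker mean and a fit without both arrays numbered 1 were added after seeing the data.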

Results

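Gene expression was measured in mouse pre-B cells transformed with BCR-ABL1, a model of Philadelphia chromosome-positive acute lymphoblastic leukaemia. The series addressed the role of Spry1 and Spry2, which encode Sprouty inhibitors of signalling from receptor tyrosine kinases to RAS and ERK. Cells with floxed alleles of both genes carried Cre-ERT2 (3 arrays) or ERT2 without the recombinase (control, 3 arrays), and all were treated with 4-hydroxytamoxifen. Expression is given as log2 RMA values. Median log2 signals of the arrays lay between 7.73 and 7.81, and correlations between arrays over all probes lay between 0.992 and 0.997. Control 1 correlated with control 2 and control 3 at 0.9923 and 0.9930, no better than with Cre-ERT2 1 (0.9931). In the fit with array weights, control 1 had the lowest weight (0.322, against 0.662 to 2.36 for the other arrays). No arrays of Cre-expressing cells without floxed alleles were analysed here, so each comparison holds both the loss of the Sprouty genes and the activity of the recombinase.

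Both floxed genes were lower in Cre-ERT2 cells. Spry2 (probe 10422227) fell from 8.42 ± 0.13 in control to 7.36 ± 0.14 in Cre-ERT2 cells (SD, n = 3 each; limma adjusted p = 0.00162), which left 47.8% of the control signal. Its log2 fold change was -1.06 (95% interval -1.26 to -0.87). Spry1 (probe 10491721) fell from 9.13 ± 0.11 to 8.29 ± 0.16 (SD, n = 3 each; limma adjusted p = 0.00462), leaving 55.7% of the signal, with a log2 fold change of -0.84 (95% interval -1.05 to -0.64). The lowest control array exceeded the highest Cre-ERT2 array by 0.82 for Spry2 and by 0.63 for Spry1, and the exact two-sided permutation p was 0.1 for each, the smallest that 3 arrays against 3 allow. With the mean level of mast cell markers as a covariate, the Spry1 change was -0.76 ± 0.14 (SE) and its adjusted p was 0.053. Testing every probe gave an adjusted p of 0.063 for Spry1, and without variance moderation the adjusted p was 0.117 for Spry1 and 0.106 for Spry2. None of the 5 other Sprouty and Spred genes passed the threshold in the main fit. Spred1, which encodes a related inhibitor of RAS activation, had the largest difference (-0.20 ± 0.05 SE, adjusted p = 0.086) and passed with dim genes left out (adjusted p = 0.0379), an intensity trend (adjusted p = 0.0364) or array weights (adjusted p = 0.0222), while Spry4 differed by -0.08 ± 0.08 (SE, adjusted p = 0.669). As a set these 5 genes did not pass (camera adjusted p = 0.459; 0 higher and 1 lower when adjusted over the list alone).

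**Figure D1:**
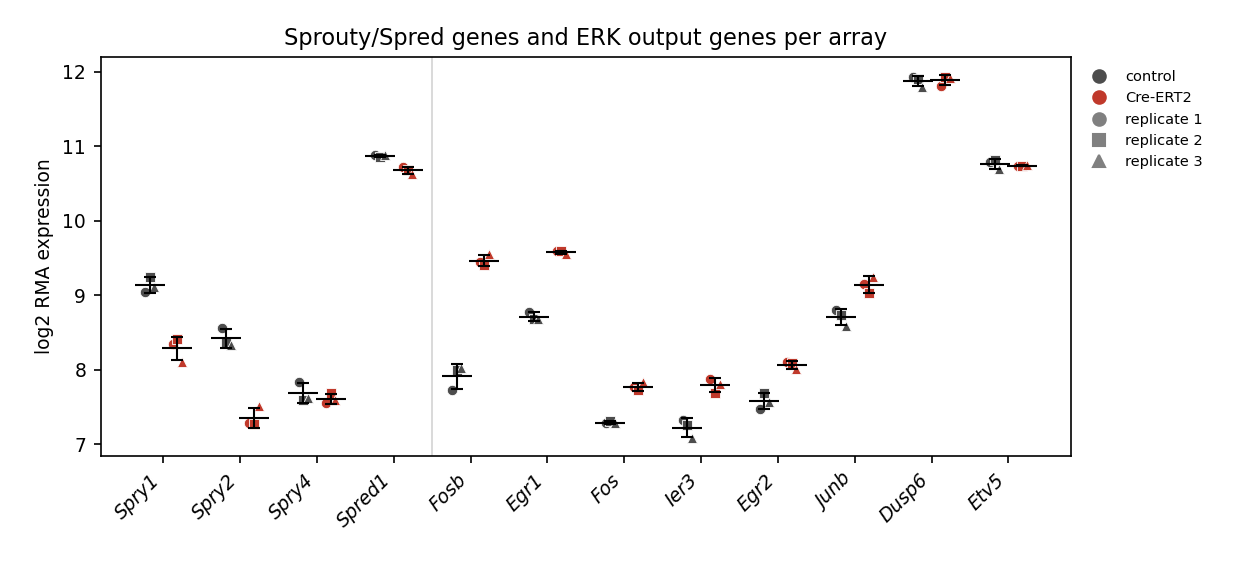
Log2 RMA expression of Sprouty and Spred genes (left of the grey line) and of ERK output genes (right) on each array. Points are single arrays, and bars give the mean and SD of 3 arrays. Spry1 and Spry2 lie lower and Fosb, Egr1, Fos, Ier3, Egr2 and Junb higher in Cre-ERT2 arrays, with no overlap between the groups, while Dusp6 is near 11.9 in both.

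Across the transcriptome, 159 of 19938 genes rose and 223 fell in Cre-ERT2 cells at an adjusted p under 0.05, and 13 of these changed at least 2-fold (10 higher, 3 lower). The largest fold change was that of Mcpt2, a mast cell protease (log2 fold change 2.45 ± 0.44 SE). Its control mean of 5.94 lay below the lower quartile of each array (6.46 to 6.55), so this size and rank are uncertain, and it was not among the genes tested when dim genes were left out. Next came the chemokine gene Ccl3 (1.98 ± 0.25), the AP-1 subunit gene Fosb (1.55 ± 0.09), the inhibitory receptor gene Lilrb4a (1.55 ± 0.31) and Id2, an inhibitor of E protein transcription factors (1.37 ± 0.11). Ly6f (1.32), the myosin light chain kinase gene Mylk (1.18), the Fc receptor gamma chain gene Fcer1g (1.17), Neurl3 (1.06) and Pir (1.003) completed the 10 largest increases. With the mast cell marker mean as a covariate, the log2 fold changes were 0.89 for Mcpt2, 0.39 for Lilrb4a, 0.48 for Ly6f and 0.28 for Fcer1g. Ms4a1, which encodes the B cell surface protein CD20, showed the largest decrease, from 8.74 ± 0.12 to 7.65 ± 0.08 (SD, n = 3 each; limma adjusted p = 6.99e-04). Besides the 2 floxed genes, the largest decreases were those of Rgs18, a regulator of G protein signalling (-1.001), Crhbp (-0.88), the tetraspanin gene Tspan6 (-0.82), the monoamine oxidase gene Maoa (-0.78), P2ry10b (-0.75), B3gnt5 (-0.74; -0.43 with the mast cell covariate) and the glutamate receptor gene Gria2 (-0.70). All 382 called genes had non-overlapping groups, as had 24.8% of all genes where chance gives 10%.

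The counts depended on single arrays and on scaling. Without 1 array they were 188 higher and 63 lower (control 1), 38 and 32 (control 2), 32 and 23 (control 3), 62 and 39 (Cre-ERT2 1), 96 and 111 (Cre-ERT2 2), or 31 and 18 (Cre-ERT2 3), and the 13 genes changed at least 2-fold became 8 without control 2 or control 3, 21 without Cre-ERT2 2 and 7 without Cre-ERT2 3. Of 45 named genes past the threshold besides Spry1 and Spry2, 32, 19 and 19 passed without control 1, 2 and 3, and 23, 33 and 18 without Cre-ERT2 1, 2 and 3. Fosb, Egr1, Atf3, Id2, Mylk, Pir, Plk2, Ms4a1, Rag2, Maoa and P2ry10b passed under each of these and under every other alternative except the model without variance moderation. Calls were also gained. Of 64 named genes that missed the threshold in the main fit, 43 passed under at least 1 alternative, 43 with array weights, 38 with dim genes left out, 34 with an intensity trend, 23 with arrays centred on their medians and 16 after a repeated quantile normalization. Higher calls outnumbered lower ones under 11 of 19 alternatives, so the excess of lower calls is unstable. Higher genes made up 41.6% of the calls with the deposited scaling, 31.2% with arrays centred on their medians (314 higher, 692 lower) and 52.5% after a repeated quantile normalization (369 higher, 334 lower).

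Some genes transcribed after ERK activation rose. Of the 23 measured members of this list, 6 rose and 0 fell, 5 had negative fold changes, and the median log2 fold change was 0.22. The 6 were the immediate early transcription factor genes Fosb (2.93-fold), Egr1 (1.83-fold; 8.71 ± 0.06 to 9.58 ± 0.02, SD, n = 3 each, limma adjusted p = 6.99e-04), Fos (log2 fold change 0.48), Egr2 (0.48) and Junb (0.43), and the stress response gene Ier3 (0.57). Adjusted over the list alone, 11 were higher and 1 was lower. The ERK phosphatase gene Dusp6 (0.01 ± 0.06 SE) and the ETS factor gene Etv5 (-0.02 ± 0.05 SE) did not pass. The list was higher by camera (adjusted p = 1.88e-11) and by fry (adjusted p = 0.0365), with adjusted p = 0.451 at an estimated correlation. The mean level of mast cell markers was also 0.775 higher in Cre-ERT2 arrays, and with it as a covariate the list median was 0.18. The list of RAS-ERK pathway components holds adaptors and kinases, but also negative regulators such as Cbl, Nf1 and Rasal3. It was shifted higher by camera (adjusted p = 0.0281; adjusted p = 0.659 with an estimated correlation). However, 0 of its 22 members passed (2 higher when adjusted over the list alone, median 0.03). Cbl (0.30, adjusted p = 0.055) and Gab2 (0.24, adjusted p = 0.085) had its lowest p-values. This call was lost without control 3, Cre-ERT2 1 or Cre-ERT2 2 and with the mast cell covariate (camera adjusted p = 0.436, median -0.02).

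Few genes of proliferation and growth passed singly in the main fit. Of 31 G2/M genes, 30 had negative fold changes (median -0.16), but only Nuf2, a kinetochore component, fell past the threshold (-0.31 ± 0.06 SE), against 18 when adjusted over the list alone. The mitotic genes Kif2c (-0.27), Cenpa (-0.27) and Birc5 (-0.25) did not pass, but did with dim genes left out (adjusted p = 0.0240, 0.0281 and 0.0428), arrays centred on their medians, an intensity trend or array weights. Of 36 DNA replication genes, 32 had negative fold changes (median -0.14), and Rrm2, a ribonucleotide reductase subunit (-0.30), and the clamp loader gene Rfc3 (-0.31) fell (13 lower when adjusted over the list alone). Of 29 MYC and ribosome biogenesis genes, 27 had negative fold changes (median -0.13) and 0 passed (8 lower when adjusted over the list alone), among them Wdr12 (-0.26) and Eif4e (-0.25), which passed under the same 4 alternatives (adjusted p = 0.0325 and 0.0292 with dim genes left out). Camera with the preset correlation placed the 3 lists lower, with adjusted p = 4.30e-08, 1.92e-06 and 5.52e-05. These became adjusted p = 0.466, 0.491 and 0.466 with an estimated correlation, and fry did not call them (adjusted p = 0.0819 each). Cholesterol synthesis genes (19 of 20 negative, median -0.13, camera adjusted p = 2.04e-04) and DNA damage and repair genes (23 of 27 negative, median -0.13, camera adjusted p = 0.00117) were also lower as lists at the preset correlation, with adjusted p = 0.466 and 0.565 at an estimated correlation. In these lists 0 genes passed singly (7 lower, and 1 higher with 10 lower, when adjusted over the list alone), and Msmo1 (-0.26) and Lig4 (-0.25) had the lowest p-values. With the mast cell marker mean as a covariate the medians were -0.12 for G2/M and -0.13 for ribosome biogenesis genes, and Nuf2 and Rfc3 were each at -0.20. The replication, cholesterol and DNA damage lists then no longer passed (camera adjusted p = 0.0813, 0.522 and 0.159). Their medians went from -0.14 (quartiles -0.20 and -0.07) to -0.08 (-0.18 and -0.02) for replication, from -0.13 (-0.17 and -0.09) to -0.08 (-0.14 and -0.05) for cholesterol, and from -0.13 (-0.20 and -0.04) to -0.12 (-0.16 and -0.08) for DNA damage genes, the last with little change in size. Cell cycle inhibitors did not pass as a list (camera adjusted p = 0.482), and Cdkn2c had the lowest p (-0.26, adjusted p = 0.070).

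**Figure D2:**
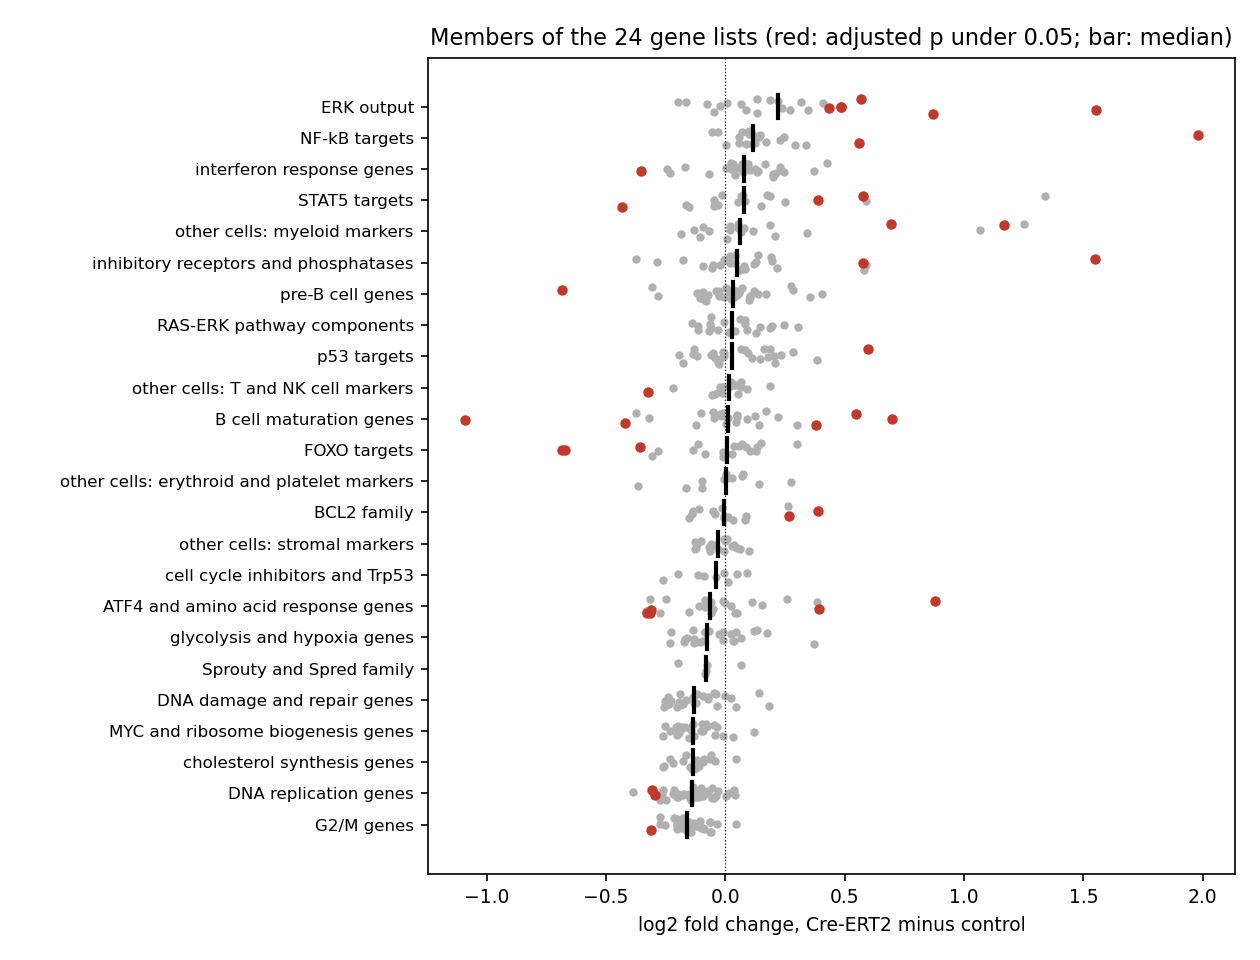
Log2 fold changes (Cre-ERT2 minus control) of the measured members of the 24 fixed gene lists. Each point is a gene, red where the adjusted p is under 0.05, and each black bar is the list median. The ERK output list has the highest median (0.22) and the G2/M list the lowest (-0.16).

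Single genes of the B cell programme passed in both directions. The only pre-B cell gene that passed, Rag2, which encodes a subunit of the recombinase that assembles antigen receptor genes, fell from 9.12 ± 0.05 to 8.43 ± 0.04 (SD, n = 3 each; limma adjusted p = 0.00162), while Irf8 (0.29) and Bach2 (0.28) did not pass. Among 25 B cell maturation genes, the interleukin 2 receptor gene Il2ra (0.70), the invariant chain gene Cd74 (0.55) and the chemokine receptor gene Ccr7 (0.38) rose. Cd74 lay just under the threshold (limma adjusted p = 0.0499). Ms4a1 (-1.09) and the complement receptor gene Cr2 (-0.42) fell. Camera called both lists higher relative to other genes (adjusted p = 0.0466 each), with adjusted p = 0.659 for pre-B and 0.466 for maturation genes at an estimated correlation. The calls were lost without control 3, Cre-ERT2 2 or Cre-ERT2 3 for both lists, without control 2 for the pre-B list and without control 1 for the maturation list. The pre-B call was also lost with the mast cell covariate (camera adjusted p = 0.1496, median 0.03 before and -0.004 after) and with the replicate block. The maturation call was also lost with the mean of all probes, repeated quantile normalization, array weights, and both arrays numbered 1 left out. The fold changes of Il2ra, Ccr7 and Cr2 were 0.38, 0.20 and -0.21 with that covariate. Adjusted over the list alone, 3 pre-B genes were higher and 1 was lower, and 5 maturation genes were higher and 4 lower. Among 20 STAT5 targets, the anti-apoptotic gene Bcl2 (0.39) and the cytokine signalling inhibitor gene Socs3 (0.58) rose and the transcriptional repressor gene Gfi1 fell (-0.43). Bcl2 was at 0.22 and Socs3 at 0.37 with the mast cell covariate, and Socs3 was at 0.34 with the mean of all probes. The list was higher (camera adjusted p = 2.04e-04; adjusted p = 0.466 with an estimated correlation; 5 higher and 1 lower when adjusted over the list alone). In the BCL2 family, Bcl2 and the pro-apoptotic gene Bmf (0.27) rose, with no call for the list (camera adjusted p = 0.146). Among 20 FOXO targets, Rag2, Trib2 (-0.67) and Ccng2 (-0.36) fell and 0 rose, with no call for the list (camera adjusted p = 0.789). Adjusted over the list alone, 2 BCL2 family genes were higher, and 1 FOXO target was higher and 4 were lower.

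Single inflammatory and stress genes also passed. Among 22 NF-kB targets, Ccl3 and the lymphotoxin gene Lta (0.56) rose and 20 had positive fold changes (median 0.12), among them Tnf (0.34, adjusted p = 0.072). Among 26 inhibitory receptor and phosphatase genes, Lilrb4a and Socs3 rose and 0 fell. Both lists were higher (camera adjusted p = 3.09e-09 and 0.00168), with adjusted p = 0.466 each at an estimated correlation. Interferon response genes were higher as a list (24 of 29 positive, median 0.08, camera adjusted p = 1.83e-05; adjusted p = 0.466 with an estimated correlation), yet the only member that passed, Ifit2, which encodes an interferon-induced antiviral protein, fell (-0.35). The p53 target list was higher (camera adjusted p = 0.00105; adjusted p = 0.565 with an estimated correlation) with a median of 0.03 and 14 of 28 fold changes positive, and the kinase gene Plk2 rose (0.60 ± 0.05 SE). Among 28 genes of the ATF4 and amino acid response, the transcription factor gene Atf3 (0.88 ± 0.07 SE) and Ddit4 (0.39), an inhibitor of mTORC1, rose, while the asparagine synthetase gene Asns (-0.31), the cysteinyl-tRNA synthetase gene Cars (-0.33) and Mthfd2 (-0.31) fell, with no call for the list (camera adjusted p = 0.585). No glycolysis or hypoxia gene passed, and that list was not called (camera adjusted p = 0.459). Adjusted over the list alone, the numbers higher and lower were 6 and 0 for NF-kB, 4 and 2 for inhibitory receptors, 6 and 3 for interferon, 5 and 0 for p53, 3 and 7 for ATF4, and 0 and 2 for glycolysis. With the mast cell marker mean as a covariate the median was 0.07 for NF-kB targets and 0.03 for interferon genes.

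Markers of mast cells, granular cells of the myeloid lineage, differed both between groups and between arrays of a group. This list was settled after the values of 44 measured candidate genes had been seen, over all of which the mean difference between the groups was 0.571. Over the 35 of them not viewed before they were written down it was 0.384. Kit, 1 of the 22 members, is also on the pre-B list. The mean log2 level of the 22 markers was 7.25 ± 0.24 in control and 8.02 ± 0.47 in Cre-ERT2 arrays (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). Array means were 7.49, 7.02 and 7.23 in control 1, 2 and 3, and 8.52, 7.59 and 7.96 in Cre-ERT2 1, 2 and 3. Of these markers, Mcpt2 and the tryptase genes Tpsab1 (0.83) and Tpsb2 (0.67) rose and 20 had positive fold changes, but the carboxypeptidase gene Cpa3 (12.02 ± 0.68 against 13.03 ± 0.49, SD, n = 3 each; limma adjusted p = 0.148) and the IgE receptor gene Fcer1a (1.69, adjusted p = 0.087) did not pass. The set was higher by camera (p = 3.09e-14; p = 0.088 with an estimated correlation). Adjusted over the list alone, 14 were higher and 0 lower. The fixed list of myeloid markers was also higher (camera adjusted p = 7.13e-04; adjusted p = 0.466 with an estimated correlation). Of its 20 members, 15 had positive and 5 negative fold changes. Fcer1g and its adaptor relative Tyrobp (0.70), both also used by mast cells, passed the threshold (3 higher when adjusted over the list alone). The lysozyme gene Lyz2 was at 1.07 (adjusted p = 0.065). The 5 negative members were Mpo (-0.18), S100a8 (-0.13), S100a9 (-0.11), Ms4a3 (-0.09) and Csf3r (-0.07), and none of these passed. With the mast cell marker mean as a covariate, the calls numbered 78 higher and 57 lower. Tpsab1 and Tyrobp were then at 0.44 and 0.32, but Lyz2 was at 1.90 (limma adjusted p = 0.0037). The myeloid list kept its call (camera adjusted p = 4.69e-04, median 0.07 against 0.06 without the covariate). The fold changes of all 382 called genes kept their sign, with a median ratio of 0.884 to those without the covariate. Of these genes, 341 kept an unadjusted limma p under 0.05. Called genes vary little within groups, which limits how far the covariate can move them, so these values do not separate causes.

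**Figure D3:**
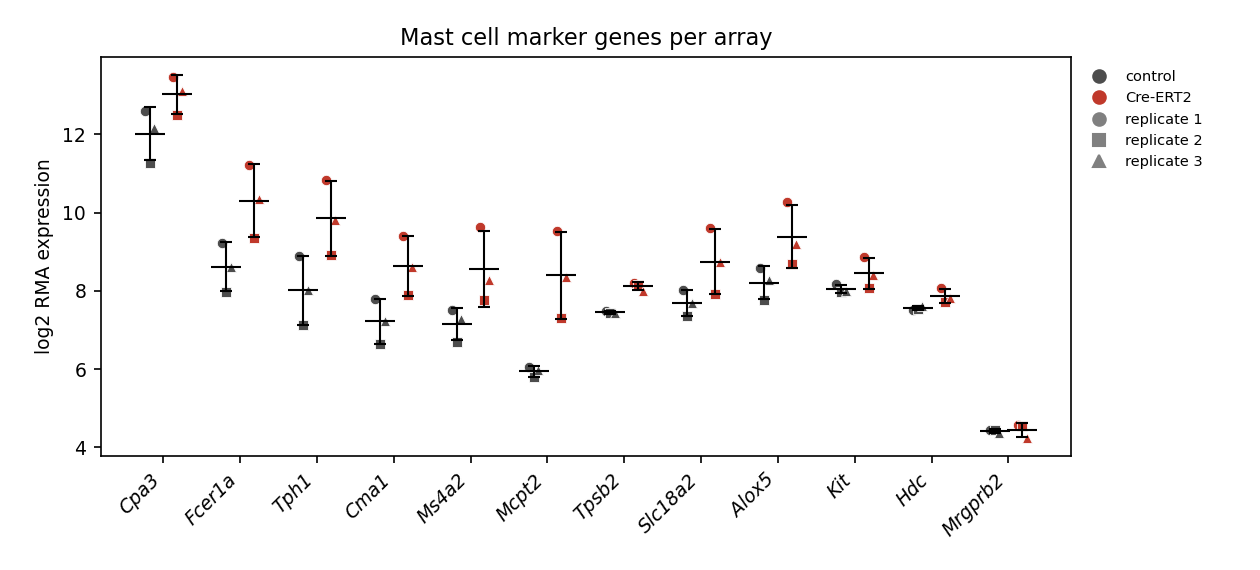
Log2 RMA expression of 12 mast cell marker genes on each array. Points are single arrays, and bars give the mean and SD of 3 arrays. Cpa3 is the brightest of those plotted, with means of 12.02 in control and 13.03 in Cre-ERT2 arrays, and most markers vary by more within a group than Tpsb2 does.

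Markers of T and NK cells, stromal cells, and erythroid cells and platelets were not called as lists (camera adjusted p = 0.389, 0.9999 and 0.228), and of their members only the NK receptor gene Klrb1c passed (-0.33). Its means of 5.68 in control and 5.35 in Cre-ERT2 arrays lay below the lower quartile of each array, so this change is uncertain, and it was not tested when dim genes were left out. In all, 15 of the 24 lists passed with a preset correlation (10 higher, 5 lower), 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 1 by fry (7 at an unadjusted p under 0.05). Camera compares a list with all other genes, whose median fold change was -0.03, and the signs of median, mean and test differed for FOXO targets (median 0.01, mean -0.08, test lower), the BCL2 family (median -0.01, mean 0.03, test higher), T and NK markers (0.02, -0.01, higher), erythroid markers (0.002, -0.01, higher) and stromal markers (-0.03, -0.03, higher).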

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

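Among the 13767 probes that name several genes or none, which enter no gene-level test, 1 probe was higher in Cre-ERT2 cells past the adjusted threshold when all probes were tested. It has the identifier 10342742 and rose from 6.46 ± 0.07 to 7.37 ± 0.06 (SD, n = 3 each; limma adjusted p = 0.0296). A second probe, 10450930, fell from 9.89 ± 0.16 to 8.84 ± 0.10 (SD, n = 3 each; limma adjusted p = 0.0456). What these probes measure was not analysed here.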

How the results depend on the processing

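None of the 45 named calls, Spry1, Spry2 and the 15 called lists changed sign. The other calls were followed only with the mast cell covariate. Of the 9 lists not called, the camera direction of 3 turned (ATF4, FOXO and stromal). Fry placed T and NK markers and stromal markers lower, where camera in the main fit placed them higher. The medians of the RAS-ERK and pre-B lists turned with the mast cell covariate, from 0.03 to -0.02 and from 0.03 to -0.004. Among lists not called, so did the medians of T and NK markers (0.02 to -0.04), FOXO targets (0.008 to -0.03) and erythroid markers (0.002 to -0.01). Spred2, which was not called, turned from 0.07 to -0.01 with the mean of all probes. Higher calls outnumbered lower ones under 11 of 19 alternatives, and lower ones outnumbered higher ones under 7. Besides some of those below, the 11 were repeated quantile normalization (369 and 334), the replicate block (296 and 285), and the fits without any 1 array except Cre-ERT2 2. Leaving out 1 array at a time gave 31 to 188 genes higher, 18 to 111 lower, 7 to 21 changed at least 2-fold, 12 to 14 lists, and log2 fold changes of -0.90 to -0.75 for Spry1 (adjusted p = 0.00992 to 0.0255) and -1.14 to -0.99 for Spry2 (adjusted p = 0.00494 to 0.0116). Genes higher and lower numbered 364 and 791 without dim genes (fewer genes tested) and 314 and 692 with arrays centred on their medians. With every probe tested, 13 probes were higher, 8 were lower and 7 changed at least 2-fold, probes that name several genes or none included. With genes changed at least 2-fold given last, genes numbered 388, 959 and 7 with an intensity trend and robust variance, 763, 1082 and 35 with array weights, 33, 23 and 7 at an adjusted p under 0.01, and 401, 833 and 20 at 0.1. Without variance moderation an ordinary linear model called 0, 0 and 0, with 3194 genes at an unadjusted p under 0.05 against 3605 in limma's moderated test. Spry1 (-0.84) missed the threshold with every probe tested (adjusted p = 0.063) and without moderation (adjusted p = 0.117), as did Spry2 without moderation (-1.06, adjusted p = 0.106). Lists past the threshold numbered 0 with an estimated correlation and 1 by fry. Apart from the smaller number of genes, samples or the threshold itself, the cause was not tested.

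Of the alternatives chosen after seeing the data, the mast cell covariate gave 78, 57 and 34 genes and a Spry1 change of -0.76 (adjusted p = 0.053), and leaving out both arrays numbered 1 gave 123 and 43. Of 45 named calls, 15 passed with that covariate and 29 without those arrays. Over all 382 called genes, the median ratio of the fold changes with and without the covariate was 0.884, so some calls were lost without a large fall in size. Since called genes vary little within groups, this ratio does not separate causes.

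With the replicate block, 35 genes changed at least 2-fold, 338 of the 382 calls were shared with its 581, and the pre-B list was not called. The numbers were not taken to pair the arrays, because the labels do not state that they mark a shared culture. Deviations from the group means correlated at 0.268 and 0.336 for numbers 1 and 2, the highest values between the groups, and at 0.0282 for number 3. Control 3 and Cre-ERT2 3 each correlated slightly better with another number (0.0304 and 0.0442). The second principal component (25.9% of variance) and the mast cell marker mean rank 1, 3, 2 in both groups, so pairing is not excluded.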

Other observations

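The list of mitochondrial ribosomal genes, the tests of the marker correlation and of array quality, the tests of the whole ERK output list and of random sets, the questions on cell-level data and on Cre arrays, and the genes named in the next paragraph were chosen only after the results were seen.

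Single genes outside the fixed lists were also called. The nuclear receptor gene Nr4a1 rose from 7.72 ± 0.13 to 8.66 ± 0.15 and the early activation antigen gene Cd69 from 11.03 ± 0.05 to 11.67 ± 0.08 (SD, n = 3 each; limma adjusted p = 0.00329 and 0.00257). The inhibitory receptor gene Ctla4 (log2 fold change 0.98), the GTPase gene Gem (0.79), Jun (0.60), Notch1 (0.67) and the costimulatory ligand gene Cd80 (0.47) rose as well. Bank1 (-0.56) and Fcrl1 (-0.54), which act in B cell receptor signalling, fell. Kmt2a (0.44), Kmt2c (0.49) and Kmt2d (0.59), which encode histone methyltransferases, rose. No set of these genes was tested. Of 77 mitochondrial ribosomal protein genes collected by name, 71 had negative fold changes (median -0.14), and 8 fell and 0 rose in limma. Mrpl47 (-0.47) and Mrps36 (-0.43) were among those that fell, and the set had a camera p = 1.70e-11, with p = 0.204 at an estimated correlation. Transcripts of the Kmt2 genes are very long and those of mitochondrial ribosomal proteins short, and RNA quality can affect long and short transcripts differently. Whether the fold changes follow transcript length was not tested here.

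Mast cell markers differed between arrays of 1 group. The within-group SD of their mean was 0.37, at least 8.16 times that of the T and NK, stromal and erythroid lists and 6.31 times that of the myeloid list. Since the markers were settled after viewing, the lowest ratio was also taken over all 44 candidates (6.4). Over the 35 not viewed before they were written down it was 4.57. This argues against a scatter shared by all genes of low signal. The T and NK, stromal and erythroid lists averaged at most 7.31 on any array, below the array medians of 7.73 to 7.81. Effects of array quality or normalization on brighter genes therefore stay open. The median pairwise correlation of the markers' within-group deviations was 0.779, as RNA of mast cells in differing shares may give. It was 0.492 over all 44 candidate genes viewed before the list was settled and 0.372 over those 35, so the choice of markers keeps this open. Mast cell genes switched on within the leukaemia cells would move together as well, and with 0 cell-level measurements analysed here the sources cannot be told apart.

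Immediate early genes were higher in Cre-ERT2 cells. With the mast cell marker mean as a covariate, the 6 called ERK output genes kept 95.5% of their median effect, 85.4% to 109% with any 1 array left out, and 95.8% with all 44 candidate genes in the covariate, and 2 of the 6 still passed. The bound set beforehand does not separate causes, since called genes vary little within groups. With all 6 arrays, 68.4% of random sets of 6 higher genes met it and 15.2% kept as much as these 6. The random sets were not refitted without 1 array, which the bound also asked for. All 23 members of the ERK output list kept 82.3%, 39.2% without Cre-ERT2 2, so RNA of mast cells in differing shares stays open. Of the 23 members, 18 had positive and 5 negative fold changes, with Dusp6 at 0.01 and Etv5 at -0.02. A candidate explanation for the rise of the 6 genes is the loss of Sprouty inhibition of ERK, and it stays a hypothesis. Activity of the Cre recombinase itself cannot be told apart from it, because 0 Cre-ERT2 arrays of cells without floxed Sprouty genes were analysed here.

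Camera with the preset correlation placed the mitotic, replication and ribosome biogenesis lists lower in Cre-ERT2 cells, but not with an estimated correlation (adjusted p = 0.466, 0.491 and 0.466), nor did fry (adjusted p = 0.0819 each). Their medians lay at or below the percentile 0.08 of random lists matched on mean signal. This argues against a trend of the fold changes with signal level as the whole source of the shifts. The matched lists themselves had medians of -0.06, -0.06 and -0.05, against -0.03 for all genes, so such a trend may give a part. The random lists drew genes independently, while these lists had estimated correlations of 0.481, 0.463 and 0.319, so the percentiles may overstate the distance. With the mast cell covariate the 96 members kept 76.7% of their median effect, but 43.4% without control 1 and up to 122% in other fits without 1 array. The mitotic, replication and ribosome biogenesis lists kept 76%, 56.3% and 95.6%. Without control 1 they kept 49.1%, 13.1% and 60.6%, and in other fits without 1 array up to 123%, 119% and 154%. RNA of mast cells in differing shares therefore cannot be told apart from a change within the leukaemia cells. Slower growth after loss of the Sprouty genes may be another explanation, and it was not tested.

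Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes higher as the real one (159), itself, and the highest of the others was 0. The same held for genes lower (223, 1 split, highest other 0) and genes changed at least 2-fold (13, 1 split, highest other 0). At an unadjusted p under 0.05 in limma, the other splits gave 427 to 1168 genes and the real split 3605. For gene lists past the threshold the real split gave 15, again with 1 split as large. The others gave 3 to 8, except the split with control 1, control 2 and Cre-ERT2 1 together, which gave 0. Camera with the preset correlation thus also called lists in splits that mix the groups. So few splits cannot give a share under 0.05.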
